A study of Arabidopsis thaliana with 4 samples.

How the data were processed

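Total RNA of 9-day-old Arabidopsis thaliana seedlings was measured on 4 single-colour Agilent arrays, with Cy3 as the dye per the labels. All seedlings carried the same genotype, and the labels put 2 arrays in each of 2 treatment groups. CHX seedlings received cycloheximide for 4 h, and CHX+DEX seedlings received cycloheximide and dexamethasone for 4 h. Replicates carry the numbers that the labels give. The labels do not say whether the replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

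The spot intensity values were made by the authors with Agilent Feature Extraction 11.5.1.1, per the file headers. Per the file headers, the processed intensity was background-subtracted and detrended within each array, and small values were replaced by a floor value. The share of non-control spots with such a replaced value ran from 9.93% to 17.7% over the 4 arrays. The flags for spots well above background, saturation and outliers are those of the same software, per the file headers. The deposited series table holds log2 values from the authors. Set against the scanner files, each of its columns equalled log2 of the processed intensity minus a constant close to that array's 75th percentile. Between 98.8% and 99.2% of probes lay within 0.01 of that constant. The column medians were -2.41 and -2.39 for CHX replicates 1 and 2, and -2.37 and -2.41 for CHX+DEX replicates 1 and 2. The labels do not state the scale of the table. The comparison settled the scale, and it showed that genes were not centred.

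From the scanner files, log2 of the processed intensity was taken and the 75th percentile of the array's non-control probes was subtracted. Control spots and 56 probes with an outlier flag on an array were left out, and spots of the same probe were averaged. No probe was saturated. Each array holds 62976 spots, of which 61657 are non-control spots of 43613 probes. The array's own annotation is old, so probes were named through their RefSeq accession in a gene table of assembly TAIR10.1. By accession 34174 probes were named, 1893 by a locus name and 239 by a symbol or synonym. A further 460 probes named several loci and 6847 named none. Probes without a single locus were left out of the gene tests, a choice made when the files were loaded, and were tested apart. The array header names another genome build, and no genome was used here, so no coordinates are given.

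A probe was kept when it was well above background on at least 2 arrays. Of the probes of a gene, the one with the highest mean over all 4 arrays stood for it, and 7559 of the 26450 loci had 2 or more probes. This left 21934 genes. They were tested in R 4.3.3 with limma 3.58.1 (lmFit and eBayes, two-sided, no covariate), with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. Files were read with Python 3.11.15 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9. Fold changes are CHX+DEX over CHX, on the log2 scale, with the standard error (SE) of the limma fit. Every such value rests on 2 arrays per group. The number of arrays limits the precision, and the median SE of a log2 fold change was 0.10. A gene dim on both arrays of a group has only a bound there. The bound is the bright group's mean against the dim group's mean of the lowest signal well above background on each array, or the gene's own signal where that was higher. Where the own signal was used on both arrays, the bound equals the measured fold. The words at least refer to this bound, which is a point value from these arrays and neither a confidence limit nor a strict minimum. Probes above that lowest signal could still be called dim. AT3G22121 was dim at -7.23 and -7.17 on the CHX+DEX arrays, where the lowest signals well above background were -7.89 and -7.34. Under normexp, which adds an offset of 50, the fold of a dim gene can lie below its bound.

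Gene lists were tested with camera in limma, with a preset correlation between genes of 0.01, two-sided and adjusted over the 27 lists. An estimated correlation was the first alternative, and fry, which asks whether a list's own genes move on balance in a single direction, was the second. With an estimated correlation camera uses the fit's 2 residual degrees of freedom, so hardly any list could pass after adjustment. A failure there therefore does not by itself argue against a list. An estimate well above the preset still means that the preset p may be too small. The 27 lists, the rule for named genes, the design of the fit and all alternatives were chosen before the data were examined. The lists hold the TCP genes that miR319 targets, TCP5-like TCP genes, reported TCP3/TCP4 targets, 4 auxin-related groups (Aux/IAA, SAUR, auxin synthesis and conjugation, HD-ZIP II), jasmonate synthesis and response, and boundary and KNOX I genes. They also hold BELL and KNOX II genes, leaf growth regulators, the mitotic cell cycle, CDK inhibitors, type-A response regulators, brassinosteroid synthesis and growth-promoting bHLH genes. The others are alpha-expansins, secondary wall genes, flavonoid synthesis, flowering regulators, the circadian clock, heat shock genes, touch and wound genes, root markers, photosynthesis markers and reference genes. Of the 330 loci on the lists, 328 had a single-locus probe. Named genes are TCP4 and the reported targets, the 5 genes with the smallest unadjusted p each way because none passed the adjusted threshold, and the 2 members with the largest absolute log2 fold change of each list. Any gene named outside this rule is said to have been named after its values were seen.

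The alternatives were quantile normalization, centring on the median, normexp background correction with an offset of 50 on the mean and local background signals, no filter on dim probes, and a filter on all 4 arrays. They also included the mean of all probes of a gene, eBayes with trend and robust settings, the authors' processed values, the replicate number as a block, leaving out each array in turn, every probe tested on its own, and other thresholds. The limma step was tested on simulated data with the real genes' means and spread, in 5 draws of 21934 genes with 200 changed genes each. Of genes changed 2-fold, 40.4% passed the adjusted threshold in the simulated comparison of CHX+DEX with CHX, and of genes changed 1.5-fold, 0.4%. The shares were 85.2% at 4-fold and 97.2% at 8-fold, and 21 unchanged genes passed over the 5 draws. These shares hold for 200 changed genes per draw. Each draw mixed folds of 1.5, 2, 4 and 8, with 250 genes per fold over the 5 draws. The larger changes make the adjusted threshold easier to pass for the 2-fold genes. With fewer changed genes the adjusted threshold is harder to pass, so a real comparison without calls does not exclude such changes.

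All 4 arrays lay on the same slide and were scanned in the same scan. The CHX arrays lay in slide row 1 and the CHX+DEX arrays in slide row 2, so slide row and treatment cannot be told apart. Replicate 1 of both groups lay in slide column 3 and replicate 2 in slide column 4. With 2 arrays against 2 there are 3 splits, so an exact two-sided permutation test cannot give a p below 0.333.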

Results

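The series profiled transcripts in Arabidopsis seedlings of the genotype jaw-D;pTCP4::mTCP4:GR. In jaw-D plants the microRNA miR319 is overproduced and the CIN-type TCP transcription factors that it targets are low. The transgene encodes a miR319-resistant TCP4 fused to the glucocorticoid receptor, which enters the nucleus when dexamethasone is given. Cycloheximide blocks protein synthesis, so transcripts that respond to dexamethasone in its presence need no newly made protein. The groups were cycloheximide alone (CHX, 2 arrays) and cycloheximide with dexamethasone (CHX+DEX, 2 arrays), each for 4 h in agitated liquid medium. Arrays with dexamethasone alone or without cycloheximide were not analysed here. Spots well above background made up 78.4% and 79.2% of non-control spots on CHX replicates 1 and 2, and 76.9% and 73.8% on CHX+DEX replicates 1 and 2. The correlation of log2 signals across genes was 0.995 between the CHX arrays, 0.993 between the CHX+DEX arrays and between 0.993 and 0.994 across the groups.

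Which transcripts responded to nuclear TCP4 without new protein synthesis was addressed by the contrast of CHX+DEX with CHX. The arrays hold no seedlings without the fusion, so an effect of dexamethasone itself cannot be told apart from one of nuclear TCP4. Genes described in earlier work as direct targets of TCP3 or TCP4 were higher as a list in CHX+DEX seedlings by camera with its preset correlation (adjusted p 4.78e-05). That call was lost with an estimated correlation (adjusted p 0.895) and with fry (adjusted p 0.362), and in limma 0 of the 12 tested members passed Benjamini-Hochberg adjustment over all genes. Of these members, 10 had a positive log2 fold change, and for 8 of them both CHX+DEX arrays lay above both CHX arrays (chance gives 33.3% separated either way). YUC5 (AT5G43890), a flavin monooxygenase of auxin synthesis, was 2.39-fold higher, with a log2 fold change of 1.26 ± 0.16 (SE, n = 2 per group). LOX2 (AT3G45140), a lipoxygenase of jasmonate synthesis, was 1.74-fold higher, at 0.80 ± 0.19, and its 4 probes gave 0.70 to 0.80. CO (AT5G15840), the photoperiod regulator of flowering, was 1.62-fold higher, at 0.69 ± 0.13. ARR16 (AT2G40670), a type-A response regulator of cytokinin signalling, was 1.36-fold higher, at 0.44 ± 0.11. A range after a log2 fold change runs over the alternatives and is given where one of them moved the value by over 1.5 times. The other members with a positive log2 fold change were SAUR65 (0.57 ± 0.16, range 0.25 to 0.76), IAA3 (0.21 ± 0.10, range 0.12 to 0.30), HAT2 (0.16 ± 0.08), SAUR50 (0.13 ± 0.09, range 0.05 to 0.19), AS1 (0.13 ± 0.12, range -0.01 to 0.24) and KRP1 (0.12 ± 0.11, range 0.04 to 0.22), and AS1 turned to -0.01 under normexp. SAUR16, at -0.27 ± 0.21 (range -0.56 to 0.03), and VND7, at -0.04 ± 0.09 (range -0.10 to 0.06), were the members with a negative value. VND7 turned to 0.06 under normexp, 0.02 without CHX replicate 2 and 0.01 without CHX+DEX replicate 1, and SAUR16 turned to 0.03 without CHX replicate 1. The microRNA genes MIR164A and MIR396B had no single-locus probe.

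The list median was 0.19. With an estimated correlation the unadjusted p of camera was 0.0429. The estimate, 0.015, was close to the preset 0.01, but that form of camera uses only the fit's 2 residual degrees of freedom. The call therefore rests on the preset form of the test, and its loss does not show correlation between the targets. Over the 15 alternatives the adjusted p of camera and fry ran from 2.03e-06 to 0.895. Some of these targets were reported from this inducible line, so the list is not independent evidence of its direction. In limma, 5 of the 12 had an unadjusted p under 0.05. Adjusted over the list alone, YUC5 (adjusted p 0.0108), CO (adjusted p 0.0247), LOX2 (adjusted p 0.0355) and ARR16 (adjusted p 0.0355) passed in limma. Here and below, that adjustment makes no allowance for the 27 lists searched. Over all genes the limma adjusted p of these genes ran from 0.586 to 0.765. Of these 4, none passed without CHX replicate 1, YUC5 and LOX2 without CHX replicate 2, YUC5 and CO without CHX+DEX replicate 1, and YUC5, CO and ARR16 without CHX+DEX replicate 2. With no filter on dim probes YUC5 alone passed, and with the mean of all probes of a gene YUC5 and CO. Leaving out an array gave at most 0.0673 for YUC5, 0.106 for CO, 0.11 for LOX2 and 0.141 for ARR16.

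**Figure D1:**
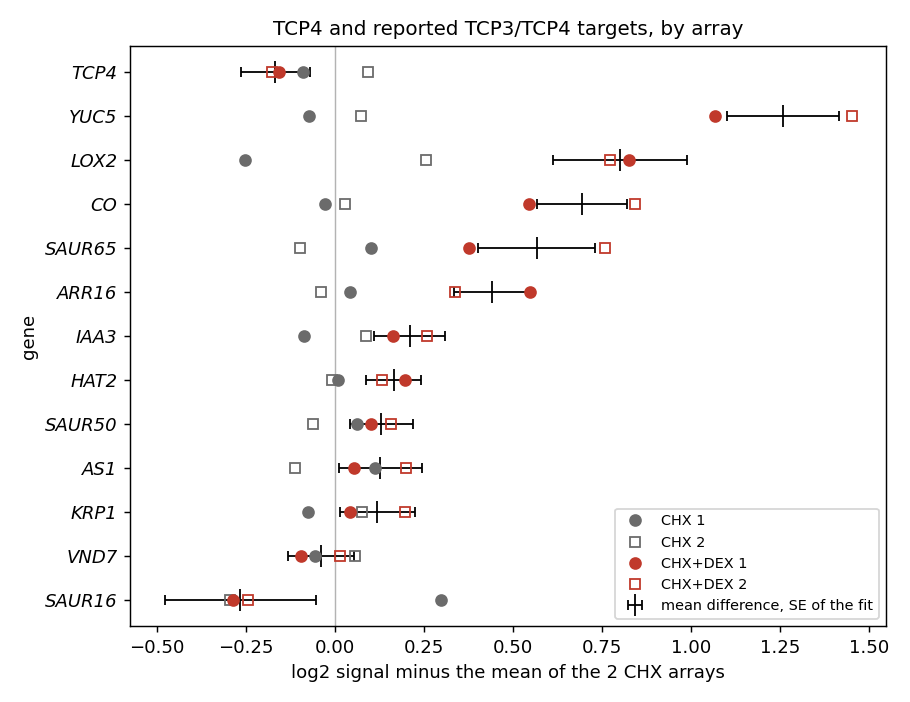
TCP4 and the 12 tested reported TCP3/TCP4 targets, with the log2 signal of each array minus the mean of the 2 CHX arrays on the x axis and genes on the y axis. Circles and squares are replicates 1 and 2 of CHX (grey) and CHX+DEX (red), and the bar is the mean difference with its SE; YUC5, LOX2, CO and ARR16 lie to the right on both CHX+DEX arrays.

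The TCP4 transcript itself (AT3G15030) had a log2 fold change of -0.17 ± 0.10 (n = 2 per group), with an adjusted p of 0.858 in limma. Its second probe gave -0.41, and the value stayed between -0.29 and -0.03 under the other settings. Whether these probes also read the transgene transcript could not be checked, so the value cannot be assigned to the endogenous gene alone. Dexamethasone acts on the protein, so this transcript does not check the labels. The 5 TCP genes that miR319 targets had a list median of 0.02 and a mean of 0.01 with a downward test (camera adjusted p 0.934), and TCP3 measured 0.17 ± 0.28 (range -0.20 to 0.55). That median turned to -0.03 under normexp and to -0.08 without CHX replicate 2 and without CHX+DEX replicate 2, and TCP3 turned to -0.06 under normexp and -0.20 without CHX replicate 2. Among the 3 TCP5-like genes (median -0.04, or -0.18 under normexp, 0.04 without CHX replicate 1 and -0.12 without CHX replicate 2, adjusted p 0.702), TCP13 measured -0.35 ± 0.09 and passed when adjusted over the list alone (limma adjusted p 0.0395). That call ended whichever array was left out (0.0663 to 0.168), with the replicate block (0.0898) and with no filter on dim probes (0.0671). TCP5 measured 0.36 ± 0.20 (range 0.14 to 0.58).

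The SAUR and Aux/IAA lists, 2 auxin-responsive families, passed upward in camera with its preset correlation (adjusted p 6.43e-04 and 0.00869). Neither passed with an estimated correlation (adjusted p 0.895 for each) or with fry (adjusted p 0.889 for each). The estimated correlations were 0.639 for SAUR and 0.15 for Aux/IAA genes, above the preset 0.01. Correlations of that size would make the preset p too small. No member of either list passed when adjusted over the list alone in limma. Of 19 tested SAUR genes, small auxin-induced transcripts, 15 had a positive log2 fold change, with a median of 0.35 that was 0.10 without CHX+DEX replicate 2 and 0.64 without CHX+DEX replicate 1. SAUR62 (0.92 ± 0.32) and SAUR63 (0.80 ± 0.30) had the largest values, which were 0.48 and 0.39 without CHX+DEX replicate 2, and 1.37 and 1.21 without CHX+DEX replicate 1. All 13 members in the 2 tandem clusters were positive, and 2 of the 6 outside them were. Of 26 Aux/IAA genes, which encode repressors of the auxin response, 21 were positive, with a median of 0.10. In limma 3 of them were higher and 2 lower at an unadjusted p under 0.05. IAA11 measured 0.39 ± 0.08 (range 0.21 to 0.43) and IAA5 0.38 ± 0.14 (range 0.20 to 0.55).

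The SAUR call ended without CHX replicate 2 (camera adjusted p 0.238) and without CHX+DEX replicate 2 (0.241), and the range over the alternatives was 2.02e-14 to 0.895. The Aux/IAA call ended without CHX replicate 1 (0.112) and without CHX+DEX replicate 2 (0.117), with a range of 0.00142 to 0.895. Both ended with no filter on dim probes (0.100). The SAUR list means were -1.71 and -1.88 on the CHX arrays and -1.72 and -1.24 on the CHX+DEX arrays. Root markers differed between the CHX+DEX arrays as well, with list means of -2.87 and -3.65, against -3.35 and -3.21 in CHX.

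The mitotic cell cycle and flavonoid synthesis lists also passed upward in camera with its preset correlation (adjusted p 0.0041 and 0.00869). Neither passed with an estimated correlation (adjusted p 0.895 for both) or with fry (adjusted p 0.889 for both). The estimated correlations were 0.629 for mitotic and 0.358 for flavonoid genes, above the preset 0.01, which would make the preset p too small. No member of either list passed when adjusted over the list alone in limma. Of 20 mitotic genes, 19 had a positive log2 fold change, with a median of 0.12. That median was 0.05 without CHX replicate 2, 0.04 without CHX+DEX replicate 1, 0.18 without CHX replicate 1 and 0.22 without CHX+DEX replicate 2. CDC20.1, an activator of the anaphase-promoting complex, measured 0.24 ± 0.12 (range 0.12 to 0.37), and the kinase gene CDKB2-2 measured 0.24 ± 0.09. Of 12 flavonoid genes, 10 were positive, with a median of 0.14 that was 0.32 without CHX+DEX replicate 2 and 0.21 without CHX replicate 1. The largest values were those of the MYB regulators PAP1 (0.56 ± 0.13) and MYB12 (0.41 ± 0.12). The enzyme genes of the flavonoid list ran from -0.21 to 0.19, and none had an unadjusted p under 0.05 in limma.

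The mitotic call ended without CHX replicate 2 (camera adjusted p 0.675) and without CHX+DEX replicate 1 (0.667), with a range over the alternatives of 2.16e-06 to 0.895. The flavonoid call ended without CHX replicate 2 (0.238) and without CHX+DEX replicate 1 (0.918), where its median turned to -0.01, and its range was 4.37e-05 to 0.918. Both ended with no filter on dim probes (0.100). The mitotic list means were -2.13 and -2.32 on the CHX arrays and -2.02 and -2.19 on the CHX+DEX arrays, so the groups overlapped, and the CHX arrays lay 0.19 apart against a mean shift of 0.12. The flavonoid list means were -2.23 and -2.35 on the CHX arrays and -1.95 and -2.30 on the CHX+DEX arrays, where the root marker means were -2.87 and -3.65.

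**Figure D2:**
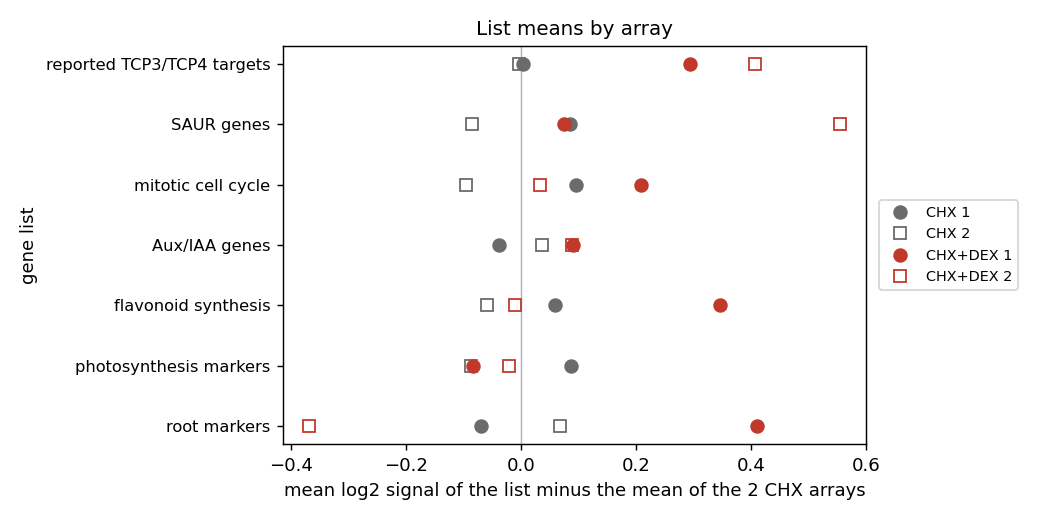
Mean log2 signal of 7 gene lists on each array, minus the mean of the 2 CHX arrays, on the x axis, with lists on the y axis. Circles and squares are replicates 1 and 2 of CHX (grey) and CHX+DEX (red); both CHX+DEX arrays lie to the right of both CHX arrays for the reported targets and the Aux/IAA genes, and the CHX+DEX arrays lie 0.78 apart for root markers.

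Other auxin and jasmonate genes did not pass as lists. Auxin synthesis and conjugation genes had a median of 0.06, or 0.14 under normexp (15 of 17 positive, camera adjusted p 0.0824), and passed in 3 of the 15 alternatives, within a range of 0.00848 to 0.895. In that list YUC5 passed when adjusted over the list alone (limma adjusted p 0.0152), but not without CHX replicate 1 (0.128) or CHX replicate 2 (0.0518) or with no filter on dim probes (0.0639), and YUC11 was at least 1.54-fold lower and not well above background in CHX+DEX, at a log2 fold change of -0.22 under normexp. HD-ZIP II transcription factor genes had a median of 0.12, or 0.05 without CHX+DEX replicate 1 (8 of 10 positive, adjusted p 0.241), with ATHB4 at 0.18 ± 0.09 (range 0.10 to 0.25) and ATHB18 at -0.18 ± 0.08. Jasmonate synthesis genes had a median of 0.09 (11 of 13 positive, adjusted p 0.0804). LOX3 measured 0.25 ± 0.12 (range 0.08 to 0.37), with -0.14 from another of its 4 probes. Jasmonate response genes had a median of 0.12 (14 of 15 positive, adjusted p 0.0607), with JAZ4 at -0.30 ± 0.23 (range -0.57 to -0.03) and VSP1 at 0.23 ± 0.19 (range -0.003 to 0.46). Past the threshold came jasmonate synthesis without CHX replicate 2 (camera adjusted p 0.00327) and jasmonate response without CHX replicate 2 (0.00404) or CHX+DEX replicate 2 (0.0095). These lists passed in 3 and 6 of the 15 alternatives, and without CHX replicate 1 their medians were 0.01 each. Without CHX replicate 2 the medians were 0.15 and 0.20, and that of jasmonate response was 0.02 without CHX+DEX replicate 1. Their ranges were 0.00327 to 0.895 and 0.00404 to 0.895, and VSP1 turned to -0.003 without CHX+DEX replicate 1.

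None of the lists of leaf development regulators passed, and their medians moved with the arrays used. KNAT3 (AT5G25220), a class II KNOX homeobox gene, was 2.41-fold higher, at 1.27 ± 0.16, and passed when adjusted over the list alone (limma adjusted p 0.0137). KNAT3 passed in that way in each of the 13 alternatives for genes (0.00031 to 0.0488). BLH2, a BELL homeobox gene named after its values were seen, measured 0.44 ± 0.09 and passed likewise (limma adjusted p 0.0374), but in only 3 of the 13 alternatives. It did not pass with the replicate block (0.0811), with any array left out (0.0893 to 0.22), or under quantile normalization (0.0772), median centring (0.0527), normexp (0.122), no filter (0.075) or eBayes trend and robust (0.118). BLH11 of the same list was at least 1.71-fold lower and not well above background in CHX+DEX, at a log2 fold change of -0.27 under normexp. The BELL and KNOX II list had a median of -0.03 and a mean of 0.04 with an upward test (camera adjusted p 0.702). That median was 0.05 without CHX replicate 1 or CHX+DEX replicate 1, -0.13 without CHX replicate 2, -0.08 without CHX+DEX replicate 2, 0.03 with the mean of all probes and 0.05 with the filter on all 4 arrays. Organ boundary and KNOX I genes had a median of -0.07, or -0.01 with no filter, -0.21 without CHX replicate 1 and -0.04 without CHX+DEX replicate 1 (adjusted p 0.574), with KNAT2 at 0.57 ± 0.15 (range 0.33 to 0.73) and CUC1 at -0.41 ± 0.13 (range -0.56 to -0.25). Among leaf growth regulators, GRF8 measured 0.82 ± 0.26 (range 0.46 to 1.18), with 0.26 from its other probe. GIF1 measured 0.49 ± 0.13. The list of such regulators, of the GRF and GIF kind, had a median of -0.01, a mean of 0.03 and a downward test (adjusted p 0.976). That median turned to 0.03 under normexp and 0.02 without CHX replicate 1, and was -0.08 without CHX+DEX replicate 2. CDK inhibitor genes had a median of 0.06, or 0.16 under normexp and 0.10 without CHX replicate 2 (adjusted p 0.359), with KRP3 at 0.42 ± 0.14 (range 0.25 to 0.59) and KRP7 at 0.18 ± 0.10 (range 0.08 to 0.28).

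In the remaining hormone and growth lists, 1 cytokinin and 2 bHLH genes passed when adjusted over the list alone. ARR6, a type-A response regulator, was lower at -0.45 ± 0.08 (limma adjusted p 0.0417), but did not pass with any array left out (0.111 to 0.205), with the replicate block (0.074), with no filter (0.0848) or with eBayes trend and robust (0.0612). The list median was -0.12 (camera adjusted p 0.635), and it turned to 0.03 without CHX replicate 2 and was -0.02 without CHX+DEX replicate 2. HEC2 was lower, at -0.94 ± 0.13, or -0.41 under normexp, and BEE3, named after its values were seen, was higher, at 0.59 ± 0.09 (limma adjusted p 0.0147 for each). Neither passed without CHX replicate 1 (0.0753 for each) or CHX replicate 2 (0.1 and 0.105), nor BEE3 without CHX+DEX replicate 2 (0.0765). The growth-promoting bHLH list had a median of -0.05 and a mean of -0.06 with an upward test (adjusted p 0.991). That median was 0.09 without CHX replicate 1 and -0.17 without CHX replicate 2, and PRE4 measured -0.99 ± 0.69 (range -1.72 to -0.26). Brassinosteroid synthesis genes had a median of 0.02 and a mean of -0.001 with an upward test (adjusted p 0.934), and the median was 0.07 under normexp and with the filter on all 4 arrays, 0.11 without CHX replicate 1, -0.09 without CHX replicate 2 and -0.01 without CHX+DEX replicate 1, with BR6OX1 at -0.38 ± 0.16 (range -0.57 to -0.09) and DWF4 at 0.24 ± 0.10 (range 0.09 to 0.32). Alpha-expansins, which loosen cell walls, had a median of 0.01 that turned to -0.08 under normexp, -0.04 with the filter on all 4 arrays, -0.05 without CHX+DEX replicate 1, -0.02 without CHX+DEX replicate 2 and -0.03 without CHX replicate 2 (adjusted p 1), with EXPA5 at 0.24 ± 0.08 and EXPA1 at 0.23 ± 0.08.

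Secondary wall genes had a median of -0.01, a mean of 0.02, an upward test and a camera adjusted p of 0.785, and the median turned to 0.05 under normexp, 0.02 with the filter on all 4 arrays and with the mean of all probes, 0.09 without CHX replicate 2, 0.04 without CHX+DEX replicate 1 and 0.05 without CHX+DEX replicate 2. NST1 was at least 1.16-fold lower, at a log2 fold change of -0.21 under normexp, and VND5 measured 0.42 ± 0.28 (range 0.05 to 0.80). Flowering regulators had a median of -0.09 and a mean of 0.14 with an upward test (adjusted p 0.934), and the median turned to 0.24 with the filter on all 4 arrays, 0.02 with no filter and 0.05 without CHX+DEX replicate 2. In that list CO passed when adjusted over the list alone (limma adjusted p 0.0247), but not without CHX replicate 1 (0.164), CHX replicate 2 (0.0655) or CHX+DEX replicate 2 (0.0556), or with no filter (0.0718). FUL measured 0.91 ± 0.43 (range 0.30 to 1.52), with -0.15 from its other probe.

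**Figure D3:**
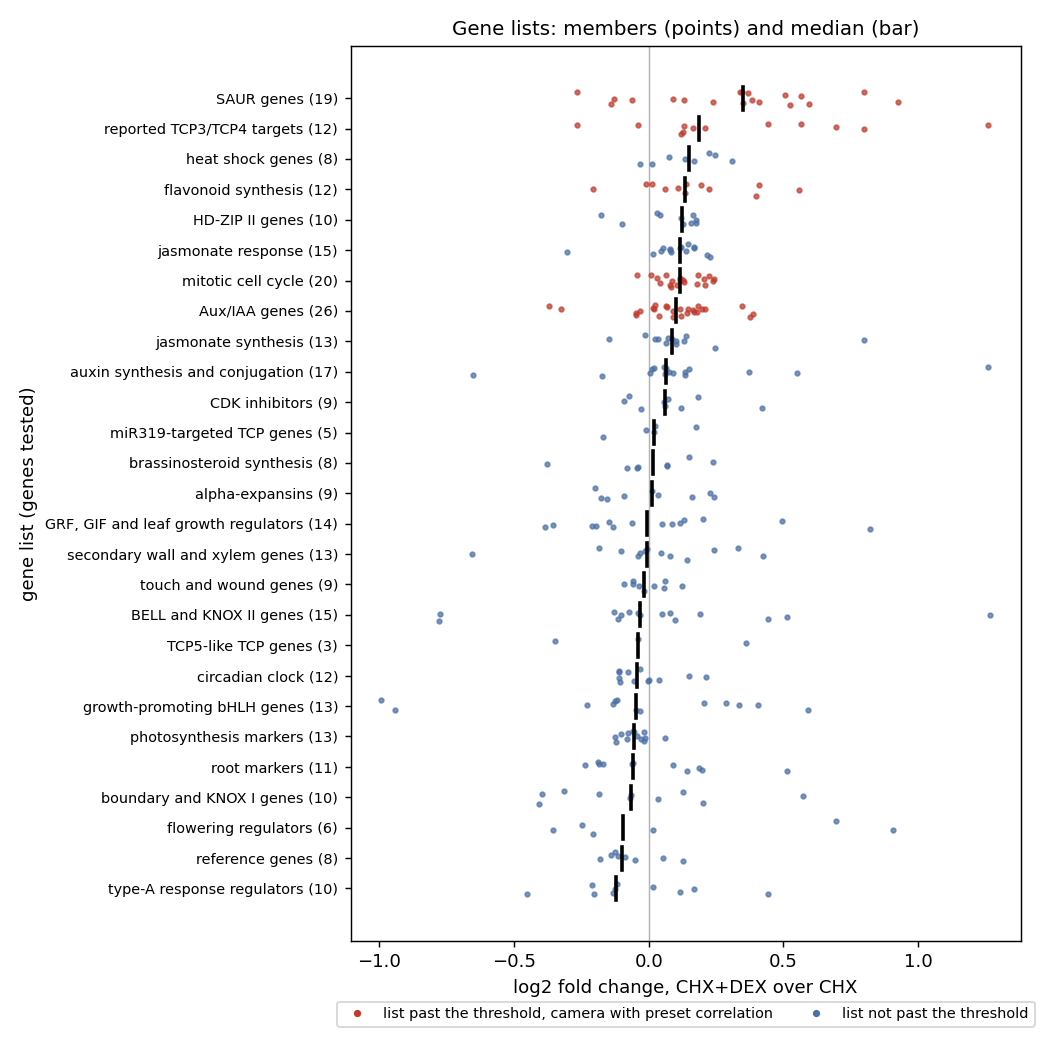
Log2 fold change (CHX+DEX over CHX, x axis) of every tested member of the 27 gene lists (y axis, number tested in brackets), as points, with the list median as a bar. Red marks the 5 lists past the threshold in camera with its preset correlation, with medians from 0.10 to 0.35. With an estimated correlation, on 2 residual degrees of freedom, 0 passed.

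Lists that check the make-up and handling of the seedlings did not pass. Root markers had a median of -0.06 that turned to 0.06 under normexp, with a mean of 0.02 and a downward test (camera adjusted p 1). NRT2.1 measured 0.51 ± 0.64 (range -0.42 to 1.45), or -0.42 without CHX+DEX replicate 1, and EXPA7 -0.24 ± 0.41 (range -0.83 to 0.36), or 0.36 without CHX+DEX replicate 2. The root list was lower without CHX+DEX replicate 1 (adjusted p 1.75e-04) and higher without CHX+DEX replicate 2 (3.59e-04), within a range of 1.75e-04 to 1. Its median was -0.21 and 0.36 in these 2 settings and 0.15 without CHX replicate 2. The photosynthesis markers RCA and GAPB each measured -0.12, with GAPB at -0.06 without CHX+DEX replicate 1 and -0.18 with the mean of all probes. The 9 probes of RCA ran from -0.45 to -0.075, and another probe of GAPB gave -0.25. Of 13 photosynthesis markers, 12 were negative, with a median of -0.05 (adjusted p 0.241), or -0.025 under quantile normalization. That list came lower without CHX replicate 2 (0.00404) and with the mean of all probes (0.0202), in a range of 0.00404 to 0.918, and its median was -0.12 without CHX replicate 2 and turned to 0.02 without CHX replicate 1.

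Heat shock genes had a median of 0.15 (7 of 8 positive, camera adjusted p 0.109), with HSFA2 at 0.31 ± 0.11 and HSP22 at 0.25 ± 0.21 (range -0.03 to 0.53). They came higher without CHX replicate 2 (0.00451), in a range of 0.00451 to 0.895. Without CHX replicate 1 their median turned to -0.01 and HSP22 to -0.03, and the median was 0.27 without CHX replicate 2 and 0.06 without CHX+DEX replicate 1. Touch and wound genes had a median of -0.02 that turned to 0.03 under quantile normalization and 0.04 under normexp, without CHX replicate 2 and without CHX+DEX replicate 1 (adjusted p 0.991), with ERF104 at 0.12 ± 0.09 (range 0.04 to 0.20) and WRKY53 at -0.09 ± 0.09 (range -0.17 to -0.02). Clock genes had a median of -0.04, or -0.08 without CHX replicate 2 (adjusted p 0.702), with PRR9 at 0.21 ± 0.13 (range 0.07 to 0.36) and CDF1 at 0.15 ± 0.13 (range 0.02 to 0.27). Reference genes had a median of -0.10, or -0.01 under normexp and -0.04 without CHX replicate 2 (6 of 8 negative, adjusted p 0.241), with SAND at -0.18 ± 0.08 and UBQ10 at -0.14 ± 0.15 (range -0.29 to 0.02), which turned to 0.02 without CHX+DEX replicate 1.

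Across all 21934 genes, limma with Benjamini-Hochberg adjustment called 0 higher and 0 lower, and the smallest adjusted p was 0.472. At an unadjusted p under 0.05 there were 644 higher and 646 lower genes, 1290 together against 1097 expected by chance. A split that mixed the groups, CHX replicate 1 and CHX+DEX replicate 2 against the other 2 arrays, gave 1246, and the split by replicate number gave 633. For 36.8% of genes both CHX+DEX arrays lay on the same side of both CHX arrays, where chance gives 33.3%. The genes with the smallest unadjusted p, none of which passed, were AT3G46370 (1.14 ± 0.08), AT1G32763, AT1G79400 (0.99 ± 0.08, or 0.41 under normexp), AT2G43670 and AT5G01860 among the higher. AT1G32763, AT2G43670 and AT5G01860 were not well above background in CHX, with bounds of 5.51-fold, 3.33-fold (its measured fold) and 3.07-fold higher. Against that dim group their log2 fold changes were 1.26, 0.87 and 0.58 under normexp, which lie below the bounds. The authors' processed values gave 6.37, 3.84 and 4.67. Among the lower they were AT5G26890, AT2G20605, AT3G22121, AT3G44790 and AT5G17540, all not well above background in CHX+DEX. They were at least 1.59-fold, 1.75-fold, 1.87-fold, 1.5-fold and 1.37-fold lower, with log2 fold changes of -0.18, -0.28, -0.17, -0.11 and -0.33 under normexp, and AT5G17540 measured -2.13 in the authors' processed values.

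At an unadjusted p under 0.01 and a fold change of at least 2, 28 genes were higher and 14 lower. Of the 28, 13 were well above background on all 4 arrays and 12 were dim on both CHX arrays. Of the 14, 1 was well above background on all 4 arrays and 12 were dim on both CHX+DEX arrays. The additive error that the scanner software estimated, in units of intensity, was 3.24 and 3.33 on the CHX arrays and 4.96 and 6.85 on the CHX+DEX arrays. YUC5 and KNAT3 were among the 28. Others, named after their values were seen, were the thionin gene THI2.1 (at least 7.18-fold, or 0.98 on the log2 scale under normexp, and at least 4.39-fold without CHX+DEX replicate 2 and 11.7-fold without CHX+DEX replicate 1), SAG29 (2.82-fold) and the cellulose synthase-like gene CSLA01 (2.29 ± 0.42, range 1.33 to 2.84). The counts became 148 and 15 with no filter on dim probes, 15 and 0 with normexp, 31 and 29 with the authors' processed values, and 26 and 1 with eBayes trend and robust. Without CHX replicate 1 they were 30 and 64, without CHX replicate 2 45 and 33, without CHX+DEX replicate 1 107 and 73, and without CHX+DEX replicate 2 109 and 22. In none of these settings did a gene pass the adjusted threshold.

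**Figure D4:**
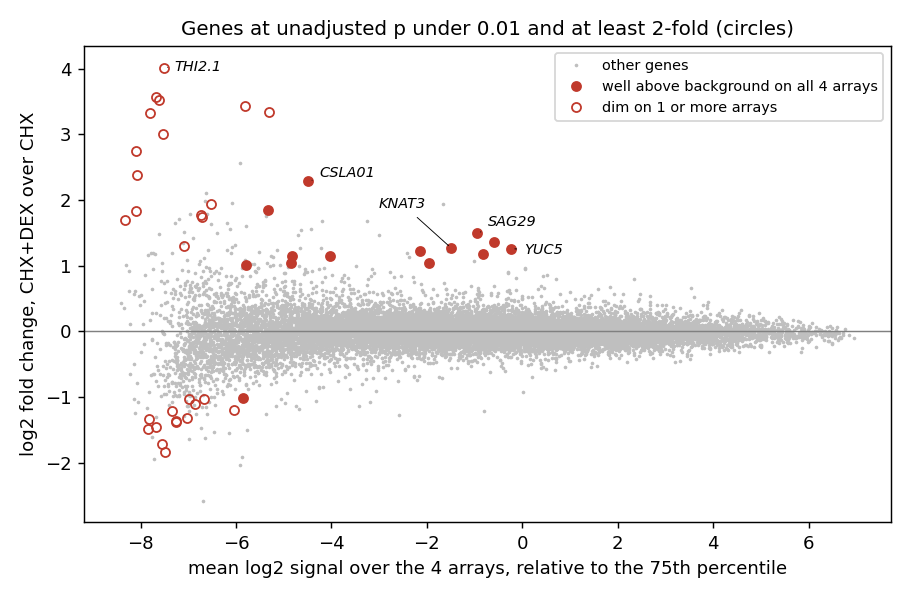
Log2 fold change (CHX+DEX over CHX, y axis) against the mean log2 signal over the 4 arrays relative to the 75th percentile (x axis) for the 21934 tested genes. Circles are the 28 higher and 14 lower genes at an unadjusted p under 0.01 and at least 2-fold, filled where the gene was well above background on all 4 arrays (13 higher and 1 lower).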

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

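Among the tests in this part, those of scaling, dim spots, slide row, SAUR co-variation, shared SAUR signal and root share were chosen only after the result was seen. The tests of other splits and of floor values were written before.

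Among the 2951 tested probes without a single locus, which no comparison of gene lists used, 1 was dim on both CHX arrays and well above background on both CHX+DEX arrays. Probe GT_A_84_P843091 was at least 9.07-fold higher in CHX+DEX, with an adjusted p of 0.276 in limma. In the opposite direction, 193 such probes were well above background on both CHX arrays and dim on both CHX+DEX arrays. In limma 0 of the 2951 passed the adjusted threshold, and 41 were higher and 146 lower at an unadjusted p under 0.05. The lowest log2 signal well above background was -8.43 and -8.26 on the CHX arrays and -7.89 and -7.34 on the CHX+DEX arrays. A fall of dim transcripts therefore cannot be told apart from the higher detection limit on the CHX+DEX arrays.

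Among genes well above background on all 4 arrays, 16 were higher and 1 lower in CHX+DEX at an unadjusted p under 0.01 and at least 2-fold. Scaling of the arrays stays open. The lowest share of higher genes under median centring or quantile normalization was 0.944, but these scalings moved the 17 genes by medians of only 0.011 and 0.007 on the log2 scale, against a median SE of 0.178, so they test nothing. Noise of dim spots stays open too. The share of higher genes was 1 in the brighter part of the genes (6 against 0), with a 95% binomial interval down to 0.541, and the dimmest part held 10 against 1. The 2 splits that mix the groups were skewed as well, at 5 against 0 and 5 against 1, all in the dimmest part. Slide row stays open, because 0 slide rows hold arrays of both groups, and so does the response to dexamethasone that the design names. The 3 splits of the 4 arrays are too few for a share under 0.05, with 17 such genes either way in the real split and 6 as the highest of the others (1 of 3 splits as large). With the filter on at least 2 arrays the real split gave 42 and the others 34 and 24, so it stood out far less. The split by replicate number, which is also that by slide column, called 1 gene past the adjusted threshold in limma, and the real split called 0. The excess was not uniform, with 31 higher and 29 lower in the authors' processed values, and 30 and 64 without CHX replicate 1, both with the filter on at least 2 arrays.

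Without the filter on dim probes, 148 genes were higher at an unadjusted p under 0.01 and at least 2-fold, against 28 with it. Of the 126 genes that this added, 97.6% (123) were well above background on at most 1 array and held the floor value set by the scanner software on at least 1 CHX array, and 70 held it on all 4 arrays. The floor value is lower on the CHX arrays, so floor values may account for nearly all of the added genes. A response to dexamethasone was not tested on these genes apart from the floor.

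The SAUR list was higher in CHX+DEX by camera with the preset correlation (adjusted p 6.43e-04), but not with an estimated correlation (adjusted p 0.895). The larger difference of the list mean within a group was 1.52 times the shift between the groups, which is consistent with SAUR genes varying together between replicate arrays. SAUR genes outside both tandem clusters had a median of -0.094 (2 of 6 positive), against 0.41 (13 of 13 positive) inside, which is consistent with signal shared between near-identical copies or with a response limited to the clusters. The root share of the seedlings stays open, since the root markers shifted by 0.021 between the groups with an SE of 0.394. A response of the clusters to nuclear TCP4 stays among the open explanations, as untested.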

How the results depend on the processing

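All alternatives here were planned, none was chosen after the result was seen, and in each limma with Benjamini-Hochberg adjustment called 0 genes, with 1290 at an unadjusted p under 0.05 in the reported setting. At an unadjusted p under 0.01 and at least 2-fold, 28 genes were higher and 14 lower. The higher count became 15 under normexp, 148 with no filter on dim probes and 16 with a filter on all 4 arrays. The lower count became 0 under normexp, 1 with a filter on all 4 arrays, 1 with eBayes trend and robust, 29 with the authors' processed values and 44 with every probe tested on its own. Leaving out each array in turn gave 30 to 109 higher and 22 to 73 lower genes, and the array left alone in its group is assumed to vary like the other group. With the replicate number as a block, 35 were higher and 22 lower, and the same 5 lists passed. Same-numbered arrays did not deviate together (r = -0.055 over genes), so the numbers are not taken to pair the arrays.

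Of the lists, 5 passed upward and 0 downward. The number upward became 7 with quantile normalization, normexp and eBayes trend and robust, and 6 with median centring, the filter on all 4 arrays and the mean of all probes. It became 1 with no filter on dim probes, 0 with an estimated correlation and 0 with fry, and 3 to 5 when an array was left out. Downward it became 1 with the mean of all probes, and 0 to 1 when an array was left out. Among the lists that check the seedlings, 1 passed with the mean of all probes and 0 to 2 when an array was left out. The reported targets had adjusted p values of 0.895 with an estimated correlation and 0.362 with fry. For SAUR, Aux/IAA, mitotic and flavonoid lists these were 0.895 and 0.889 each, and 0.100 each with no filter on dim probes. Leaving out an array in turn gave 2.02e-14 to 0.241 for SAUR, 0.00564 to 0.117 for Aux/IAA, 2.16e-06 to 0.675 for the mitotic and 4.37e-05 to 0.918 for the flavonoid list.

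Of named genes, normexp turned AS1 to -0.007, VND7 to 0.056 and TCP3 to -0.057. Leaving out an array in turn gave SAUR16 -0.562 to 0.029, VND7 -0.097 to 0.017, TCP3 -0.20 to 0.55, VSP1 -0.003 to 0.46, HSP22 -0.033 to 0.53, NRT2.1 -0.42 to 1.45, EXPA7 -0.83 to 0.36 and UBQ10 -0.293 to 0.015. The other 1192 values of named genes under an alternative kept their sign, and none passed the adjusted threshold. The cause was not tested, except that no filter adds dim genes and a left-out array leaves fewer samples. Signal over background limits what can be seen of dim genes, since the lowest log2 signal well above background was -8.43 and -8.26 on the CHX arrays and -7.89 and -7.34 on the CHX+DEX arrays.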

Other observations

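The gene families and the groups in this part, and their tests, were chosen only after the result was seen.

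Phi-class glutathione S-transferases, enzymes of detoxification, tended to lower values in CHX+DEX, with 11 of 12 tested members negative and a median log2 fold change of -0.17. GSTF2 measured -0.41 ± 0.10, GSTF3 -0.41 ± 0.10, GSTF12 -0.39 ± 0.09 (range -0.45 to -0.20), GSTF7 -0.38 ± 0.09 and GSTF6 -0.31 ± 0.09 (SE). Of 130 families named by a shared symbol with at least 10 tested genes, this was the only family past the threshold in camera with the preset correlation (adjusted p 0.00342). For this family the estimated correlation was 0.144, above the preset 0.01. With an estimated correlation, on 2 residual degrees of freedom, camera gave an adjusted p of 0.994 (unadjusted p 0.11), and 0 families passed. Signal shared between probes of similar members was not checked. The median ran from -0.14 under normexp, where 4 members were positive, to -0.27 without CHX replicate 1, and none of these genes passed in limma over all genes.

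Genes of trichome development had a median of 0.14, with 10 of 16 positive. The median was 0.06 without CHX+DEX replicate 1 (9 positive) and 0.24 without CHX+DEX replicate 2 (13 positive). ZFP8 (1.18 ± 0.15) and GIS (1.04 ± 0.22), zinc finger genes of trichome initiation, had the largest values. Both CHX+DEX arrays lay above both CHX arrays for 8 of the 16 and below for 2, where chance gives 33.3% either way. TCL1 (0.46 ± 0.16, range 0.24 to 0.66) and CPC (0.28 ± 0.08), which encode repressors of trichome fate, were also positive. Of the 16, 6 were negative, among them EGL3 with the lowest value, GL2, GL3 and TTG1 (-0.22 ± 0.08). The unadjusted p of camera was 0.0149 with the preset correlation and 0.416 with an estimated correlation, which was 0.373. ZFP8 and GIS were among the 28 higher genes in limma at an unadjusted p under 0.01 and at least 2-fold. The group was chosen after these values were seen, so its test and its separation count are not independent evidence. None of these genes passed the adjusted threshold in limma.

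Dim on both CHX arrays and well above background on both CHX+DEX arrays were 15 genes, and 269 showed the opposite. The lowest log2 signal well above background was higher on both CHX+DEX arrays than on both CHX arrays. Of the 15, the cellulose synthase-like gene CSLG2 had a bound of 10.7-fold higher, which is its measured fold. The bounds were 7.18-fold for THI2.1 and 4.63-fold for the tubby-like gene TLP4. The 2 CHX+DEX arrays differed widely for these genes. Without CHX+DEX replicate 1 the bounds were 5.19-fold, 11.7-fold and 2.88-fold, and without CHX+DEX replicate 2 they were 22.2-fold, 4.39-fold and 7.45-fold. Under normexp, with its offset of 50, the log2 fold changes against the dim CHX group were 1.60, 0.98 and 1.23, all below these bounds. For TLP4 the authors' processed values gave 5.95.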
